A study of Arabidopsis thaliana with 12 samples.

How the data were processed

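Total RNA of Arabidopsis thaliana plants was measured on expression arrays in 12 samples, 6 from the wild type (WT, ecotype Columbia 0) and 6 from the pete1 mutant in the same ecotype, which lacks an isoform of plastocyanin. Per the labels, both genotypes were grown on MS medium, a standard culture medium for plants. The labels number the samples 1 to 6 within each genotype and say nothing of the tissue, the plant age or whether the samples came from separate plants. The p-values therefore measure only the spread between these samples, which may be technical.

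The deposited values are intensities on a linear scale, 1 value per probe and sample, for 3439 probes. The array reader, the background correction and the scaling that the authors used are not given in the sources used here. The deposited intensities have a mean close to 1 in each sample, no value below 0, zeros in every sample and an upper cap, so the scaling was taken from the values and its method stays unknown. No measure of background or of signal quality per spot was used here, and the number of samples limits the precision.

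Probe names came from the platform annotation and were updated through gene identifiers with the RefSeq gene table of the TAIR10.1 assembly. Of the 3439 probes, 692 had 1 gene (690 of these matched a locus), 870 had several genes and 1877 had none in that annotation. Genes were named only from probes with 1 gene, and no coordinates are given because the deposited values name no genome build.

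The smallest positive intensity (4.74e-05) was added to every value before taking log2. The sample medians differed by up to 2.25-fold, above the limit of 1.2-fold set for using the values as they were, so the log2 values were quantile normalised. A fold change is therefore on the quantile-normalised log2(intensity + offset) scale, and its size can differ widely from that in the deposited intensities. Each probe was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3, statmod 1.5.0), pete1 against WT, two-sided, with Benjamini-Hochberg adjustment over all 3439 probes and a threshold of 0.05. Sample-level summaries were compared with a two-sided exact permutation test, over all 12 samples and, chosen after seeing the data, over averages of consecutive numbers and within equal numbers. Probes at 0 in a group are given as listed values without a fold.

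The design, the alternatives, 19 gene lists with 266 loci and the rule for named genes were fixed before the data were examined. Named genes were PETE1, PETE2 and CYTC6A, the 8 largest rises and 8 largest falls among single-gene probes past the threshold, and the 2 members with the smallest p from each list with at least 5 measured members (4 if the list passed its test). PETE1, PETE2 and CYTC6A had no probe of their own in the annotation and are not analysed here. Only 18 of the 266 loci had a probe of their own, and only the plastid ribosome list had at least 5, so the other 18 lists were not tested. A further 10 lists were made from the probe annotation before any gene's values were seen. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted by Benjamini-Hochberg over the planned list alone or, for the added lists, over all 11.

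The numbers of the samples were checked for structure. Deviations from the group mean correlated at 0.221 to 0.452 between the WT and pete1 samples of the same number in all 6 such pairs. The shared numbers in the titles therefore pair the samples, and a fit with the number as a block was run. That fit took the 6 numbers as independent, so it made no allowance for likeness between consecutive numbers. Consecutive numbers within a genotype (1 and 2, 3 and 4, 5 and 6) had a median correlation of deviations of 0.255, below the 0.5 set for averaging, and were kept apart in the fit of 12 samples. With the 10th percentile of all intensities (0.0514) as the offset, that median was 0.549, above 0.5, so the choice between 12 samples and averages turned on the offset. Their Spearman correlations of intensities (0.955 to 0.980) nonetheless lay above those of other samples of a genotype (0.849 to 0.901), and fits that average them or treat them as a random block (duplicateCorrelation, chosen after seeing the data) were run.

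The fits were tested on simulated data with the means and spreads of the 3439 normalised probes, for pete1 against WT. There were 200 changed genes, 100 at 2-fold and 100 at 4-fold. Apart from these, both genotypes had the same mean for each probe. The gap in deposited medians between the genotypes, and how normalisation handles it, were therefore not simulated. Nor was the correlation between equal numbers, and each figure came from 1 random draw. With independent samples, the fit of 12 samples recovered 61% of the 2-fold and 95% of the 4-fold changes and called 4 unchanged probes. Noise was also shared within consecutive numbers, at the correlation of 0.810 that duplicateCorrelation estimated from these data. With that noise and no changed gene, the fit of 12 samples called 66 probes, the random block 2 and the averages 1. With 200 changed genes and that noise, the fit of 12 samples called 171 unchanged probes and the random block 7, and the averages recovered 16% of the 2-fold and 60% of the 4-fold changes. The alternatives were the intensities as deposited, median centring, a larger offset, leaving out dim probes or probes at 0, the number as a block, other averages, a variance trend, array weights and leaving out samples.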

Results

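The arrays compared the transcripts of WT Arabidopsis and of the pete1 mutant, which lacks an isoform of plastocyanin, the small copper protein that carries electrons to photosystem I. The comparison asks which transcripts differ in abundance when that isoform is missing. Each genotype had 6 samples, numbered 1 to 6, and 3439 probes were measured in each. The median deposited intensity was 0.544 ± 0.0641 (SD, n = 6) in WT and 0.309 ± 0.0208 in pete1, and no sample of a genotype overlapped the other (exact permutation p = 0.00216, two-sided, with all 12 samples taken as independent). With averages of consecutive numbers, 3 against 3, the exact permutation p was 0.1, the smallest that 3 against 3 allows. With the genotypes exchanged only within equal numbers, and the 6 numbers taken as independent, it was 0.0312, also the smallest possible. A WT sample held 191 ± 15.6 probes at 0 and a pete1 sample 263 ± 19.9. Transcripts of PETE1, the mutated gene, and of PETE2 and CYTC6A were not analysed here, so the genotype labels were not checked against the missing transcript.

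**Figure D1:**
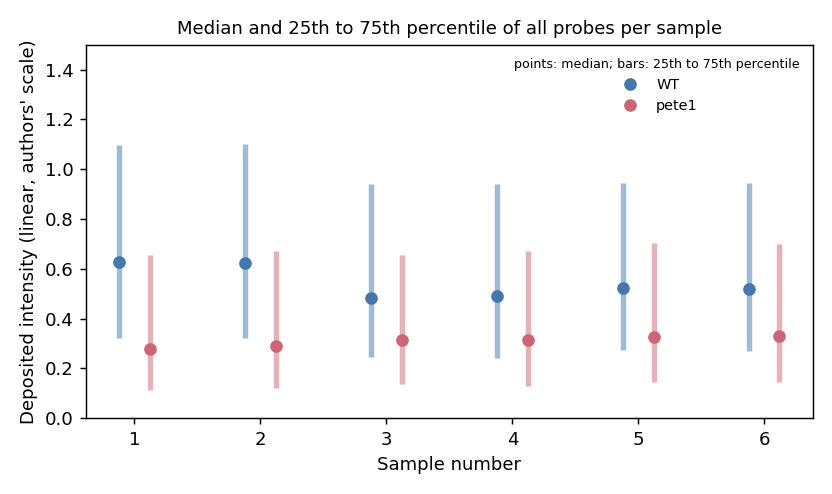
Median (points) and 25th to 75th percentile (bars) of the deposited intensities of all probes in each WT and pete1 sample, on the authors' linear scale, by sample number. The WT medians lie between 0.485 and 0.627 and the pete1 medians between 0.279 and 0.331.

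Transcripts of the photosynthetic genes LHCB1.5 and PRK were more abundant in pete1 than in WT. LHCB1.5 (LHB1B2, AT2G34420), a chlorophyll-binding protein of the photosystem II antenna, rose from an intensity of 10.1 ± 2.3 (SD, n = 6) in WT to 31.1 ± 3.62 in pete1, a log2 fold change of 1.19 after normalisation (limma adjusted p = 0.000743). Whether transcripts of related genes also bind the LHCB1.5 probe was not checked here. PRK (AT1G32060), phosphoribulokinase of the Calvin cycle, rose from 0.565 ± 0.119 to 1.14 ± 0.273, a log2 fold change of 1.58 (limma adjusted p = 0.000977). AILP1 (AT5G19140), an aluminium-induced protein, rose from 0.157 ± 0.0213 to 0.256 ± 0.0252, a log2 fold change of 1.85 (limma adjusted p = 2.46e-05). AT1G11820, a glycosyl hydrolase, was at 0.153 ± 0.0742 in WT and was listed at 0 in all 6 pete1 samples (limma adjusted p = 1.74e-09). These 4 calls held when consecutive sample numbers were treated as a random block, a fit chosen after seeing the data, with limma adjusted p of 0.0185 for LHCB1.5, 0.00865 for PRK, 0.0102 for AILP1 and 2.35e-07 for AT1G11820. When the quantile-normalised values of consecutive numbers were averaged to 3 against 3, only the call of AT1G11820 held (limma adjusted p = 0.00255). Those of LHCB1.5, PRK and AILP1 were lost (limma adjusted p of 0.144, 0.158 and 0.0517). With the small offset, the zeros of AT1G11820 lay at -14.36 on the log2 scale, and its call was lost too in averages with a larger offset or with the pair as a block, fits chosen after seeing the data (limma adjusted p of 0.0941 and 0.0905). All 4 genes kept their direction in the intensities as deposited. The log2 fold changes there were 1.65 for LHCB1.5, 1.0 for PRK and 0.71 for AILP1. Median centring adds 0.81 to every log2 fold change as deposited, so it was no separate check of these rises. AT1G11820 stayed lower after it. In averages of the intensities as deposited, a fit chosen after seeing the data, the call of PRK was lost (limma adjusted p = 0.0682). Those of LHCB1.5, AILP1 and AT1G11820 held there (limma adjusted p of 0.0419, 0.0461 and 0.000666).

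**Figure D2:**
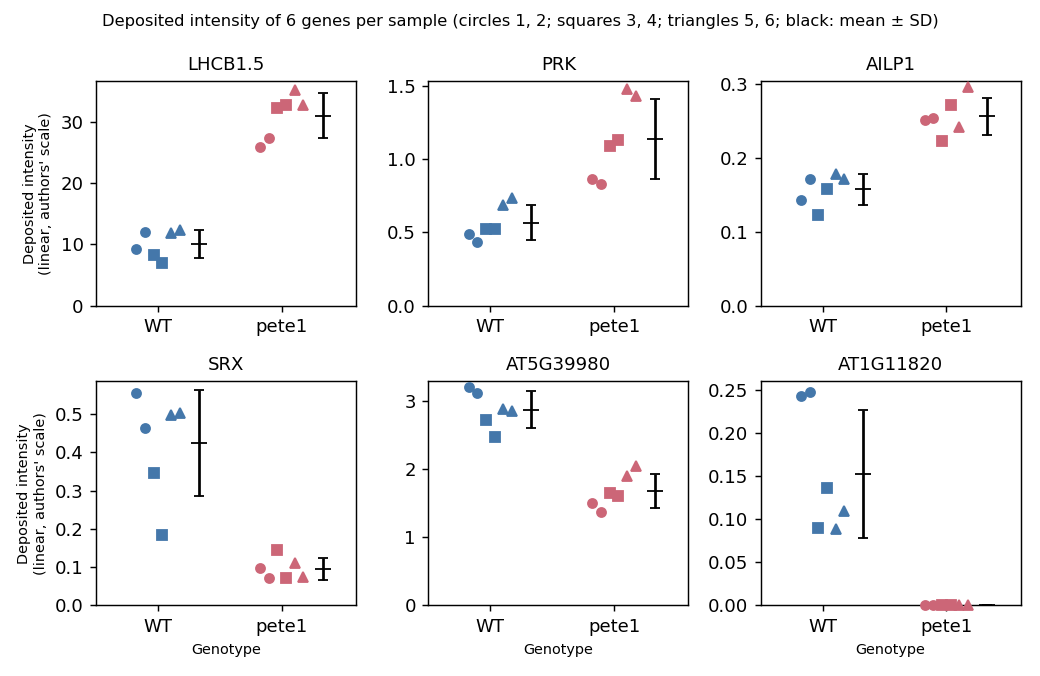
Deposited intensity (linear, authors' scale) of 6 genes in each WT and pete1 sample, with a marker shape for each pair of consecutive numbers and, in black, the mean ± SD of 6 samples. LHCB1.5, PRK and AILP1 lie higher in pete1, SRX and AT5G39980 lie lower, and AT1G11820 is at 0 in all 6 pete1 samples; after median centring, AT5G39980 lies 0.03 higher on the log2 scale.

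Over all probes, 746 of 3439 passed the threshold of limma, 369 higher and 377 lower in pete1. Among the probes with 1 gene, 54 rose and 86 fell. The split between rises and falls followed the scaling, with 115 rises and 1746 falls in the intensities as deposited, where the median log2 fold change of all probes was -0.73, and 664 rises and 357 falls after median centring. The count also followed how samples were counted. It was 163 (95 rises and 68 falls) with consecutive numbers as a random block, and 7 (no rises and 7 falls) when they were averaged to 3 against 3, where 563 probes had an unadjusted p under 0.05. Of the 39 called genes examined one by one, 38 lost their call in those averages. All 39, AT1G11820 among them, lost it in averages with a larger offset or with the pair as a block. No probe passed limma in either (620 and 591 had an unadjusted p under 0.05). Averages of the intensities as deposited, a fit chosen after seeing the data, gave 363 probes, 12 rises and 351 falls. There 22 of the 39 genes lost their call and another 10 turned in direction.

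AILP1 was dim in WT, at 0.157 against a 25th percentile of at least 0.2438 in each WT sample. The normalisation widened its log2 fold change to 1.85, from 0.71 as deposited. The other large rises were likewise mostly of dim probes, whose fold changes the normalisation widened. AT5G27860 had the largest, 4.86 on the log2 scale, although its intensity went from 0.0574 ± 0.0249 to 0.0990 ± 0.0203 and its log2 fold change as deposited was 0.91. AT1G50000 rose by 2.73, AT2G39000 by 2.22 and AT4G13550 by 1.59 on the log2 scale, against 0.76, 0.23 and 0.21 as deposited. FATB (AT1G08510), an acyl-ACP thioesterase of plastid fatty acid synthesis, rose by 1.91 (limma adjusted p = 0.00165). As deposited its log2 fold change was 0.60, without a call (limma adjusted p = 0.0539). AT4G31930 rose by 1.53, and by 1.07 as deposited. Of the 6 genes other than AILP1, only AT4G13550 kept its call with consecutive numbers as a random block (limma adjusted p = 0.0262). The call of AT5G27860 was lost without pete1 sample 4 (limma adjusted p = 0.0548), and that of AT2G39000 was kept in 5 of 12 fits that left out a sample.

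Among the large falls, AT2G46190 was at 0.538 ± 0.261 in WT and was listed at 0 in 4 of 6 pete1 samples. AT4G09970 was at 0.126 ± 0.0550 in WT and was likewise listed at 0 in 4 pete1 samples. AT4G22830 was listed at 0 in all 6 pete1 samples and in 2 WT samples, and its call was lost with the sample number as a block (limma adjusted p = 0.0611). The calls of AT4G09970 and AT4G22830 were kept in 3 and 2 of 12 fits that left out a sample. AT5G51670 fell from 0.313 ± 0.0911 to 0.0293 ± 0.0226, a log2 fold change of -2.08, and AT5G48130 from 0.321 ± 0.100 to 0.0535 ± 0.0337, a log2 fold change of -1.39. AT4G38040 and AT2G47680 had log2 fold changes of -1.44 and -1.29. The normalisation narrowed these 4 falls, which as deposited were -3.86 for AT5G51670, -2.75 for AT5G48130, -2.28 for AT4G38040 and -2.41 for AT2G47680 on the log2 scale. With consecutive numbers as a random block, the calls of AT5G51670 and AT5G48130 held (limma adjusted p of 0.0399 and 0.0397), and those of AT2G46190, AT4G09970, AT4G22830, AT4G38040 and AT2G47680 did not.

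Of the plastid ribosome genes, the only fixed list with enough measured members, RPS6 (AT1G64510) rose over all genes tested, with a log2 fold change of 1.44 (limma adjusted p = 0.0323). Adjusted over the list alone, 3 of the 6 members rose, RPS6, RPL17 (0.64 on the log2 scale) and RPS10 (0.85). As deposited, RPS10 was lower in pete1 (-0.22), and RPL17 was at 1.90 and 1.97 in pete1 1 and 2 but between 0.737 and 0.916 in the other pete1 samples, against 0.871 to 1.09 in WT. RPL29 was listed at 0 in every sample. The list's median log2 fold change was 0.50, and -0.14 as deposited. It did not pass camera (p = 0.0888, and p = 0.112 with an estimated correlation), and it passed with the sample number as a block (p = 0.0442) but not with consecutive numbers averaged (p = 0.116, and p = 0.0603 with the pair as a block). The call of RPS6 was lost with the random block (limma adjusted p = 0.183), was kept in 7 of 12 fits that left out a sample, and its direction turned as deposited (-0.05). Across all 19 fixed lists, 4 of the 18 measured loci rose and 1 fell over all genes tested, against 3 rises and 3 falls as deposited.

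Among 22 genes of photosynthesis and its assembly, 5 rose, 2 fell and 15 did not pass over all genes tested, and the same counts held adjusted over the list alone. As deposited, 3 rose and 9 fell, against 115 rises and 1746 falls among all 3439 probes. Beside LHCB1.5 and PRK, both of them also members of fixed lists, the rises were of ATAB2 (1.03 on the log2 scale), PIFI (0.73) and AT3G29185 (0.38), all 3 of which were lower in pete1 as deposited. PSB27, a photosystem II assembly factor, had a log2 fold change of -0.97, and NdhS, a subunit of the chloroplast NADH dehydrogenase-like complex, of -0.36; both lay above 0 after median centring. ATAB2, PIFI, AT3G29185, PSB27 and NdhS were chosen after their values were seen, and none kept its call with the random block. The call of AT3G29185 was also lost with the sample number as a block (limma adjusted p = 0.0738). The list did not pass camera (adjusted p = 0.450, and adjusted p = 0.664 with an estimated correlation), and it passed after median centring (adjusted p = 0.00596).

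None of the other 9 added lists passed camera, with adjusted p between 0.332 and 0.697. Of 19 pentatricopeptide repeat proteins, which bind organelle RNA, 3 fell and none rose over all genes tested and adjusted over the list alone. As deposited 12 fell, as did 1746 of all 3439 probes. AT5G39980 fell from 2.88 ± 0.270 to 1.68 ± 0.253, a log2 fold change of -0.69 (limma adjusted p = 0.00491), and AT3G26630 had a log2 fold change of -0.94. AT5G39980 kept its call with the random block (limma adjusted p = 0.0381), but its log2 fold change was 0.03 after median centring. The third, AT3G49740, was chosen after its values were seen (-0.55). With the sample number as a block, the calls of AT3G26630 and AT3G49740 were lost (limma adjusted p of 0.0534 and 0.0836). Of 6 mTERF proteins, which act on organelle transcripts, AT3G46950 rose by 0.68 on the log2 scale and mTERF9 (AT5G55580) had a log2 fold change of -0.77. Neither kept its call with the random block, and that of mTERF9 was kept in 2 of 12 fits that left out a sample.

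Of 16 genes in the added list named plastid metabolism, 4 rose and 1 fell. As deposited 1 rose and 6 fell, against 115 rises and 1746 falls among all 3439 probes. Whether each member of the list, such as the beta-ketoacyl synthase AT2G04540, acts in the plastid was not checked. The rises were of FATB, of AT2G04540 (0.44 on the log2 scale), a beta-ketoacyl synthase that was lower as deposited, and of AT1G17160 (0.79) and CBL (1.1), and the fall was of AT1G31220 (-0.37); AT1G17160, CBL and AT1G31220 were chosen after their values were seen. With the random block only AT1G17160 kept its call (limma adjusted p = 0.0475), and with the sample number as a block those of CBL and AT1G31220 were lost (limma adjusted p of 0.0897 and 0.0820). Of 10 genes of cell division, 3 rose and none fell over all genes tested, and 3 rose and 1 fell adjusted over the list alone, whereas none rose and 6 fell as deposited. The 3 rises were of the histone H3 genes AT1G09200 (1.1 on the log2 scale, limma adjusted p = 0.00786) and AT1G13370 (0.80), and the kinesin gene AT1G21730 (0.55), which was chosen after its values were seen. AT1G09200 kept its call with the random block (limma adjusted p = 0.0493) but not as deposited (0.28 on the log2 scale, limma adjusted p = 0.346), and the direction of AT1G13370 and AT1G21730 turned as deposited.

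Of 6 antioxidant genes, SRX (AT1G31170), sulfiredoxin, fell from 0.424 ± 0.137 to 0.0949 ± 0.0289, a log2 fold change of -1.08 (limma adjusted p = 0.0159). As deposited its log2 fold change was -2.12. It passed in averages of those intensities (limma adjusted p = 0.0419), a fit chosen after seeing the data with 12 rises and 351 falls. CCS (AT1G12520), the copper chaperone of superoxide dismutase, rose by 0.68 on the log2 scale, and its log2 fold change was -0.61 as deposited. Neither call held with the random block, where limma gave an adjusted p of 0.361 for SRX and 0.217 for CCS, and that of CCS was lost with the sample number as a block (limma adjusted p = 0.0626). Of 10 plastid folding factors and proteases, AT1G68660 rose by 0.24 on the log2 scale, a direction that turned as deposited, and AT5G35100 did not pass (-0.69, limma adjusted p = 0.0850). With the sample number as a block the call of AT1G68660 was lost (limma adjusted p = 0.112) and AT5G35100 passed (limma adjusted p = 0.0253), as it did not with the random block or the averages (limma adjusted p of 0.525 and 0.360). Of 7 cell wall genes only AT1G11820 passed, and CSLA01 (0.44) did not, although it passed with the sample number as a block (limma adjusted p = 0.0114), and not with the random block or the averages (limma adjusted p of 0.387 and 0.469), and its log2 fold change was -0.50 as deposited. Of 6 floral and reproductive regulators only AGL103 passed (-0.27), a call that was lost with the sample number as a block (limma adjusted p = 0.0799), and LAS (-0.35) did not. None of 5 genes of pigment and tetrapyrrole synthesis passed, among them HEMA3 (0.56) and CHLP (0.24, AT1G74470). As deposited none of the antioxidant, mTERF, folding and protease, cell wall, floral or pigment genes rose, and 3, 4, 6, 4, 4 and 1 of them fell. Among all 3439 probes, 115 rose and 1746 fell as deposited, so these counts do not mark out the lists.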

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

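Of 78 groups of 6 values tested for a sample far from the others, 5 were picked out. Chance picks out about 5% of groups only if the 6 values are independent, which the likeness of consecutive numbers puts in doubt. The 78 include AT1G11820 and AT4G22830 in pete1, at 0 in every sample, which could not be picked out. AT4G09970 was at -7.42 in WT 3 on the normalised log2 scale, with the other WT samples between -4.07 and -3.15. SRX was at -2.85 in WT 4, with the others between -1.85 and -1.35. CCS was at -2.23 in pete1 2, above the others at -2.87 to -2.63. AT5G35100 was at -1.40 in pete1 6, below the others at -0.48 to -0.34. The mean deposited intensity of WT 2 was 1.07, above the other WT samples at 1.05 to 1.06.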

How the results depend on the processing

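Alternatives marked as added were chosen after seeing the data, and the cause of each change was not tested unless stated. Against 746 probes, the intensities as deposited gave 1861 and the averages of consecutive numbers 7. Of the added alternatives, the random block gave 163, the averages with the pair as a block 0 (591 at an unadjusted limma p under 0.05) or with a larger offset 0 (620 likewise), the averages as deposited 363, samples 1, 3 and 5 gave 9, samples 2, 4 and 6 gave 12, and samples 1, 2 and 3 gave 157. The sample number as a block, a fit that took the 6 numbers as independent, gave 743, 559 of them shared. Other alternatives gave 549 to 1021, and leaving out 1 sample 550 to 722. The fixed list counts went from 0 to 1 with that block, with numbers 3 apart averaged, and without samples 3 and 4 (added), and stayed at 0 on leaving out 1 sample. Of the added lists, 1 passed after median centring, against 0, and 0 on leaving out 1 sample. Fry, which tests a list against no change and not against other genes, as camera does, is another question; by it 1 fixed and 4 added lists passed. Signs reversed as deposited for AT1G64510 (-0.0461), CCS (-0.61), AT2G04540 (-0.27), AT1G68660 (-0.28), AT1G13370 (-0.0298), NdhS (0.00667), AT3G29185 (-0.44), PIFI (-0.52), ATAB2 (-0.27) and AT1G21730 (-0.43), and for CSLA01 (-0.50), which had no call. Averaging consecutive numbers leaves each log2 fold change as it is, so the averages were no second check of these signs. After median centring, signs reversed for AT5G39980 (0.0283), NdhS (0.82) and PSB27 (0.0339). With 12 samples as deposited, the reversed direction passed limma for AT3G29185, PIFI, AT1G21730, AT2G04540, CCS and AT1G68660 (limma adjusted p of 0.00336, 0.00531, 0.00881, 0.0221, 0.0243 and 0.0268). After median centring it passed for NdhS (limma adjusted p = 0.00354). Of the 39 called genes examined, 9 lost their call with the number as a block, 38 with averages and 29 with the random block, and 2 of the 6 others gained one with the number as a block. Results for PETE1 and PETE2 were not run, and the fixed list had too few members without dim probes or probes at 0. Camera was not run with the random block. With no background measure used, the signal over background behind the dim probes is unknown. In fits that left out 1 sample, the calls of CCS, mTERF9, AGL103, CBL and AT4G22830 were kept in 2 of 12, of AT1G68660, AT1G31220 and AT4G09970 in 3, of AT3G49740 in 6, of AT3G29185 in 9 and of AT3G26630 in 10.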

Other observations

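The 4 tests on consecutive numbers and on the sample medians and the count over splits that keep consecutive pairs whole were chosen after the results were seen, and the other counts over splits before.

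The 746 probes past the threshold of limma with 12 samples against 7 with averaged numbers raised the question of what the numbers stand for. Each of the 6 consecutive pairs had a Spearman correlation of at least 0.955, above the highest of the other 24 sample pairs of a genotype (0.901), which is consistent with consecutive numbers being duplicates of 1 hybridisation. With 3 samples per genotype, a set that holds a pair (1, 2 and 3) gave 157 probes, against 9 (1, 3 and 5) and 12 (2, 4 and 6) where none did. The count thus differed with a pair held at the same number of samples. All 3 counts lay far below 746, and only 1 set with a pair was run. How much of the loss comes from fewer samples alone therefore stays open. What the pairs are, such as duplicate spots, repeated hybridisations or plants grown together, stays open.

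In the deposited intensities the WT median was 1.76 times the pete1 median, while the mean of a WT sample (1.06 ± 0.00789, SD, n = 6) was 1.08 times that of a pete1 sample (0.977 ± 0.0362), also without overlap (exact permutation p = 0.1 for averages of consecutive numbers, the smallest that 3 against 3 allows). A larger share of signal in a few bright probes does not explain the whole gap, since without the brightest 1% of probes the ratio of median to mean still differed 1.43-fold and the genotypes did not overlap. At least 170 spots were listed at 0 in each WT sample, so a background of 1 size was not left in every WT spot as listed. How those zeros arose is unknown, so they cannot speak to a background in the spots above 0. Such a background, the scaling by the authors, the RNA or labelling of the samples and the genotype itself stay open and were not tested.

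Of 100 splits of the 12 samples, 1, the real one, gave 746 probes, and the highest of the others gave 38, which excludes chance only if the 12 samples are independent. Nearly all of those splits break consecutive pairs. Of the 10 splits that keep all 6 pairs whole, 1, the real one, gave as many, and the highest of the others gave 168, but 10 splits are too few for a share under 0.05. Of the 32 splits that part the 6 pairs of equal numbers, 1, the real one, gave as many, and the highest of the others gave 4; those other splits put both genotypes in each group.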
